A study of Mus musculus with 4 samples.

How the data were processed

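Gene expression was measured with Affymetrix mouse arrays in bone marrow cells of Mll-AF4stop knock-in mice, which carry a fusion construct that stays silent until the Cre recombinase acts on it. Per the labels' protocols, the mice received 5-fluorouracil, a drug that kills cycling blood cells, and 5 days later the marrow was infected outside the animal with a retrovirus carrying Cre and GFP or with a control GFP retrovirus. GFP-positive cells were sorted 2 days after infection and grown for 14 days in lymphoid culture, and 20 ng of total RNA was amplified with a NuGen Ovation kit before hybridization. The sample labels give 2 arrays per group, Cre-GFP 1 and 2 and control 1 and 2. The series' design text calls the control virus MIG-Cre while the sample labels call it a GFP control; the sample labels were followed. If the control virus also carried Cre, the comparison would not be of an activated against a silent fusion. The labels do not say whether arrays of a group came from separate mice or cultures. The p-values of single genes therefore measure only the spread between these 4 arrays, which may be technical. The control virus carried no Cre per the sample labels, so the activated fusion and the presence of Cre cannot be told apart.

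The authors deposited 1 table of probe set intensities on a linear scale, made with RMA, a method that normally corrects background, equalizes the arrays by quantiles and summarizes the probes, per the submitters' processing notes; a software version is not given in the sources used here. The table held 22690 probe sets for the 4 arrays. Median intensities were 87.7 and 85.1 in Cre-GFP 1 and 2 and 85.9 and 86.2 in control 1 and 2. Each value was put on the log2 scale and not normalized again. Scanner files, detection calls and scan dates were not used here, so scan batches were not tested, and the number of arrays limits the precision. The median 95% confidence interval of a gene's log2 fold change reached 0.37 to either side. As RMA is normally run, it brings the arrays to nearly the same distribution, so a shift shared by most genes would not be seen, and its summary compresses differences at low intensity, so folds of dim genes are understated.

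Probe sets were named through the platform annotation. It gave exactly 1 gene symbol for 20393 probe sets, several for 691 and none for 1606, and the last 2 kinds, which include 64 control probe sets, were left out of gene tests. Of the probe sets with 1 symbol, 20364 matched the RefSeq gene table (GRCm38.p6) by gene number, with 0 symbols changed; that table served for names and for the order of neighbouring genes. Each of 12394 genes was represented by its probe set with the highest mean over the 4 arrays. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Positive log2 fold changes mean higher in Cre-GFP. Errors given with ± after a log2 fold change are limma's standard errors (SE), with 2 arrays per group.

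Before the data were examined, the groups, tests, alternatives, named genes and 19 gene lists were fixed. The lists were the HoxA cluster, an MLL fusion program outside HoxA, MLL, AF4 and DOT1L complex subunits, stem cell and early progenitor markers, B lineage, T lineage, NK and cytotoxic, neutrophil and granule, monocyte and macrophage, dendritic and MHC class II, mast cell, basophil and eosinophil, erythroid, megakaryocyte and platelet, and stroma and endothelium markers, cell cycle, p53 targets and DNA damage, interferon response, Myc targets and ribosome biogenesis, and immediate early and stress genes. They came from general knowledge and not from these arrays. Of 399 list memberships, 350 were measured, 5 lay only on probe sets with several genes, and the others were not named by the tables used here. Each list was tested with limma's camera (preset correlation 0.01, two-sided), adjusted over the 19 lists, and again with a correlation estimated per list and with fry. With the preset correlation, camera compares a list's members with all other genes. Its p-value then rests on the spread over genes and does not measure the spread between arrays. With an estimated correlation, camera also takes its degrees of freedom from the fit, which left 2, so few lists could pass. Members were also adjusted over the list alone, and these calls do not allow for the 19 lists examined.

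Named genes were the 12 with the largest change in each direction among those past the threshold, with groups that did not overlap and a mean in the higher group at or above the median of all genes. Where fewer passed, places were filled by the smallest unadjusted p under the same other conditions. Up to 4 members per list with the smallest p, all measured HoxA genes, and Kmt2a, Aff1, Meis1, Cdkn1a, Il7r, Csf1r and Mpo were added. A gene named outside this rule is marked as chosen after its values were seen.

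The procedure was tested on simulated data for the same 12394 genes, with 2 arrays per group, variances drawn from limma's fitted prior and 200 changed genes in each of 5 runs. At an adjusted p under 0.05 it recovered 2.0% of genes changed 1.41-fold, 48.2% of those changed 2-fold, 97.2% at 4-fold and 99.6% at 8-fold, and called a mean of 6 unchanged genes per run. These sizes were planted in equal numbers. The adjustment is milder when many genes change strongly, so the shares do not carry over to arrays with fewer such genes. In the real arrays Grtp1, 6.19-fold higher, had a limma adjusted p of 0.15. A list shifted by more than any real list median was called by camera in 5 of 5 runs. Unshifted lists were called in 1 of 90 tests. The simulated errors were independent between genes, while correlations estimated in the real arrays reached 0.41 (monocyte and macrophage list). The simulation therefore does not show how often camera calls unshifted lists of correlated members, or finds smaller shifts. Alternatives were quantile normalization again, centring on each array's median, leaving out the dimmest 40% of genes, eBayes without trend or with robust estimation, the mean of a gene's probe sets, leaving out shared probe sets, raising values to each array's 20th percentile, the replicate number as a block, leaving out each array, all probe sets, an ordinary two-sample test with pooled variance, and 1.5-fold in place of 2-fold. Shared probe sets here are all those with the suffix _x_at, _s_at or _a_at, which need not match several genes.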

Results

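The series compared bone marrow cells given a Cre-GFP retrovirus, meant to switch on a silent Mll-AF4 fusion, with cells given a control GFP retrovirus, after 14 days of lymphoid culture. The labels conflict on whether the control virus also carried Cre, and if it did, the comparison is not of an active against a silent fusion. Each group had 2 arrays and 12394 genes were tested. MLL-AF4 joins the histone methyltransferase MLL (Kmt2a) to AF4 (Aff1), a subunit of a transcription elongation complex, and is found in infant acute leukemia. Kmt2a itself read 8.73 and 8.05 on the log2 scale in Cre-GFP 1 and 2 and 8.66 and 8.47 in control 1 and 2, a log2 difference of −0.18 ± 0.26 (SE, n = 2 per group). Aff1 read 9.31 and 8.54 against 9.18 and 9.19, a difference of −0.26 ± 0.27. The differences of Kmt2a and Aff1 were 0.16 and 0.12 without Cre-GFP 2 and −0.52 and −0.64 without Cre-GFP 1, and that of Kmt2a was −0.085 without control 1 and −0.27 without control 2. The 2 probe sets of Kmt2a and 3 of Aff1 did not pass the threshold. The sequence of the construct was not analysed here, so these probe sets may lie outside it and then check nothing about its activation.

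The comparison asked which genes differ where Cre was given to act on the fusion construct. Hoxa5, Hoxa7, Hoxa9, Hoxa10 and Hoxa11, homeobox transcription factors of blood progenitors, and their partner Meis1 stood higher in both Cre-GFP arrays than in either control array. Hoxa5 was 3.16-fold and Hoxa9 2.39-fold higher, and Meis1, the homeodomain protein that binds DNA together with Hoxa9, was 3.31-fold higher. Igf2bp3, an RNA-binding protein of fetal tissues and leukemia, was 3.29-fold higher, and Lmo2, a bridging factor in early blood transcription complexes, 3.14-fold. In the other direction, the B lineage, p53 target and interferon response lists fell as groups in camera, calls that were lost with an estimated correlation (adjusted p = 0.42 for each). No B lineage member passed over its list alone, while 5 p53 targets and 3 interferon response genes did. Calls of single genes rest on the lists fixed in advance, since in limma 0 genes passed over all 12394 (600 at an unadjusted p under 0.05), while 2 passed by an ordinary two-sample test.

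**Figure D1:**
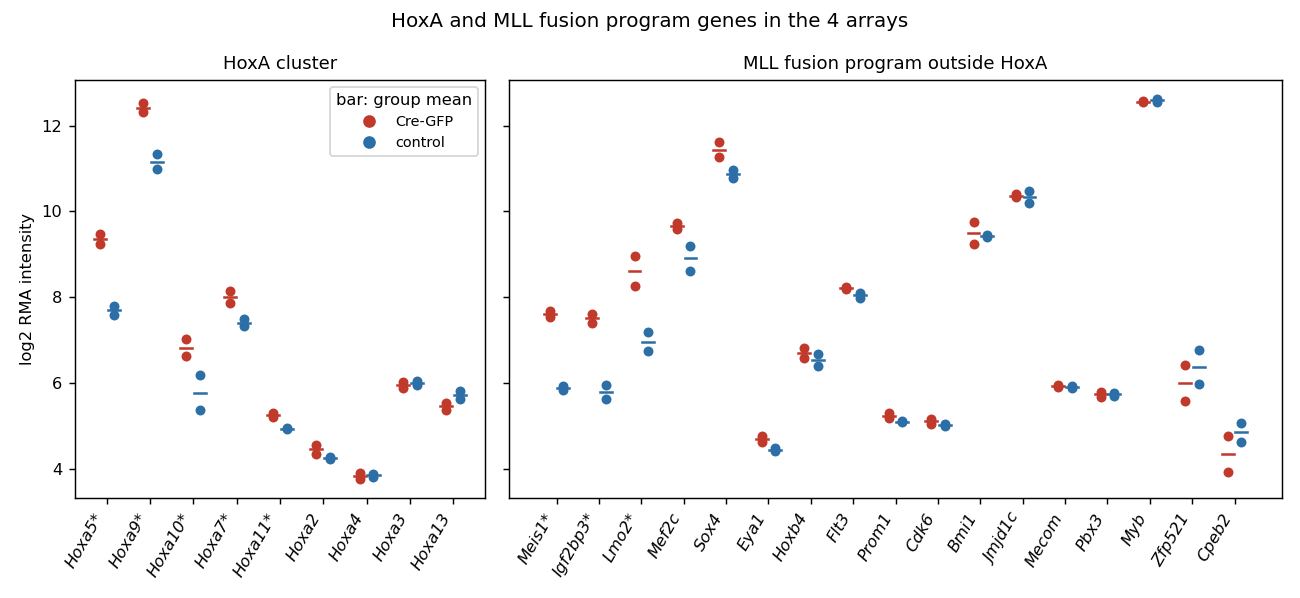
Each point is an array's log2 RMA intensity for a gene, with Cre-GFP in red and control in blue and the bar at the mean of the 2 arrays. An asterisk marks the 5 HoxA genes and 3 other program genes with an adjusted p under 0.05 over the list alone; the Hoxa9 arrays lie at 12.31 and 12.52 against 11.33 and 10.98.

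Of the 9 HoxA genes measured, 5 rose when adjusted over the list alone and 0 passed over all genes. Hoxa5 differed by 1.66 ± 0.18 and Hoxa9 by 1.26 ± 0.18 on the log2 scale, with adjusted p = 8.2e-04 and 0.0018 over the list. Hoxa10 was 2.06-fold higher (1.04 ± 0.28), Hoxa7 differed by 0.59 ± 0.17 and Hoxa11, a dim gene, by 0.32 ± 0.10, or 0.15 with dim values raised to each array's 20th percentile. Hoxa5 and Hoxa9 passed over the list without any single array, while Hoxa10 (0.64 without control 2), Hoxa7 and Hoxa11 did not without either Cre-GFP array. Hoxa7 also missed without control 2, and Hoxa11 without either control array and with dim values raised. Differences of the other 4 did not pass, with Hoxa13 at −0.27 ± 0.13 (−0.17 without control 1), Hoxa2 at 0.20 ± 0.11, Hoxa3 at −0.05 ± 0.12 and Hoxa4 at −0.01 ± 0.10. Hoxa2 differed by 0.10 without Cre-GFP 2, 0.30 without Cre-GFP 1 and −0.0031 with dim values raised. Hoxa3 and Hoxa4 turned to 0.03 and 0.06 without Cre-GFP 2 and to 0.07 and 0.01 with the mean of their probe sets, and ranged from −0.12 to 0.06 when single arrays were left out. Hoxa10 also missed with the replicate number as a block. A second Hoxa9 probe set differed by only 0.45 ± 0.19. The list median was 0.32 and the list passed camera (adjusted p = 3.6e-05), a call lost with an estimated correlation (adjusted p = 0.42 with an estimated correlation). That median was 1.15 without the dimmest 40% of genes and 0.15 with dim values raised, and the list passed camera in each of these settings.

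Of the 17 measured genes of the MLL fusion program outside HoxA, 13 were higher in Cre-GFP and 3 rose when adjusted over the list alone. These were Meis1 (1.73 ± 0.13, adjusted p = 2.1e-04 over the list), Igf2bp3 (1.72 ± 0.16) and Lmo2 (1.65 ± 0.28). These 3 passed over the list without any single array. The 3 other Igf2bp3 probe sets differed by 0.35 to 0.52, and without shared probe sets Igf2bp3 (0.35) did not pass and Meis1 and Lmo2 were not measured. Mef2c, a transcription factor of lymphoid and leukemic progenitors, differed by 0.74 ± 0.24 (0.45 without control 2) and Sox4, another progenitor transcription factor, by 0.56 ± 0.18 (−0.13 to 0.50 on its other probe sets), without passing. The receptor Flt3 (0.16 ± 0.16, and 0.10 without control 2), Myb (−0.03 ± 0.12) and Pbx3 (−0.00 ± 0.11), named after their values were seen, did not pass either, and Myb and Pbx3 lay between −0.06 and 0.06 when single arrays were left out. The list median was 0.14 (camera adjusted p = 3.6e-05, and adjusted p = 0.42 with an estimated correlation). It was 0.087 without Cre-GFP 1, 0.37 without the dimmest genes and 0.069 with dim values raised, passing camera each time. In the same arrays the monocyte and macrophage list was higher in Cre-GFP, with a median of 0.11, and the B lineage list lower, with a median of −0.28.

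The B lineage list had 22 of its 26 measured members lower in Cre-GFP, and 14 of the 26 were lower in both Cre-GFP arrays than in either control array. Spib, an Ets-family transcription factor of B and plasmacytoid cells, differed by −2.26 ± 0.57. Cd79b and Cd79a, the signalling chains of the B cell receptor, differed by −1.70 ± 0.43 and −0.80 ± 0.21, and Pou2af1, a B cell coactivator of octamer-binding factors, by −1.68 ± 0.49. Il7r, the interleukin-7 receptor chain, differed by −0.94 ± 0.40. Without Cre-GFP 2 the differences of Spib and Pou2af1 were −1.41 and −0.89, and that of Il7r was −0.35 without control 2 and −1.53 without control 1. None of the 26 passed over the list alone. As a group the list fell (median −0.28, camera adjusted p = 1.1e-06, and adjusted p = 0.42 with an estimated correlation). The median was −0.52 without Cre-GFP 1 and −0.45 without control 1, and the list also passed camera when Cre-GFP 1 and control 2 were set against Cre-GFP 2 and control 1, with a median of 0.28, as large as that between the groups.

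Of the 22 measured p53 targets and DNA damage genes, 19 were lower in Cre-GFP and 5 fell when adjusted over the list alone. Ddit4, a stress-induced inhibitor of mTORC1, was 2.02-fold lower (−1.01 ± 0.18), Trp53inp1, a p53-induced cofactor of p53, 1.88-fold lower (−0.91, −0.57 without Cre-GFP 2 and −0.34 on its other probe set) and Ccng1 1.53-fold lower. Gadd45a differed by −0.74 ± 0.10 at values under each array's 20th percentile, and by −0.0031 once such values were raised to it. Zmat3, a p53-induced RNA-binding protein named because it also passed, was 2.00-fold lower (a log2 difference of −0.66 without control 2). Without Cre-GFP 2, 0 of these 5 passed over the list. Without Cre-GFP 1 Ccng1 and Zmat3 missed, without control 1 Ccng1, and without control 2 Ddit4, Ccng1, Trp53inp1 and Zmat3. With the replicate number as a block, Ccng1, Trp53inp1 and Zmat3 missed. Cdkn1a, the cell cycle inhibitor p21 and a standard p53 target, differed by −0.47 ± 0.19 (−0.31 without control 2) and did not pass. The list median was −0.24 (camera adjusted p = 1.1e-07, and adjusted p = 0.42 with an estimated correlation). It was −0.37 without Cre-GFP 1 and −0.13 without Cre-GFP 2, passing camera in both cases.

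**Figure D2:**
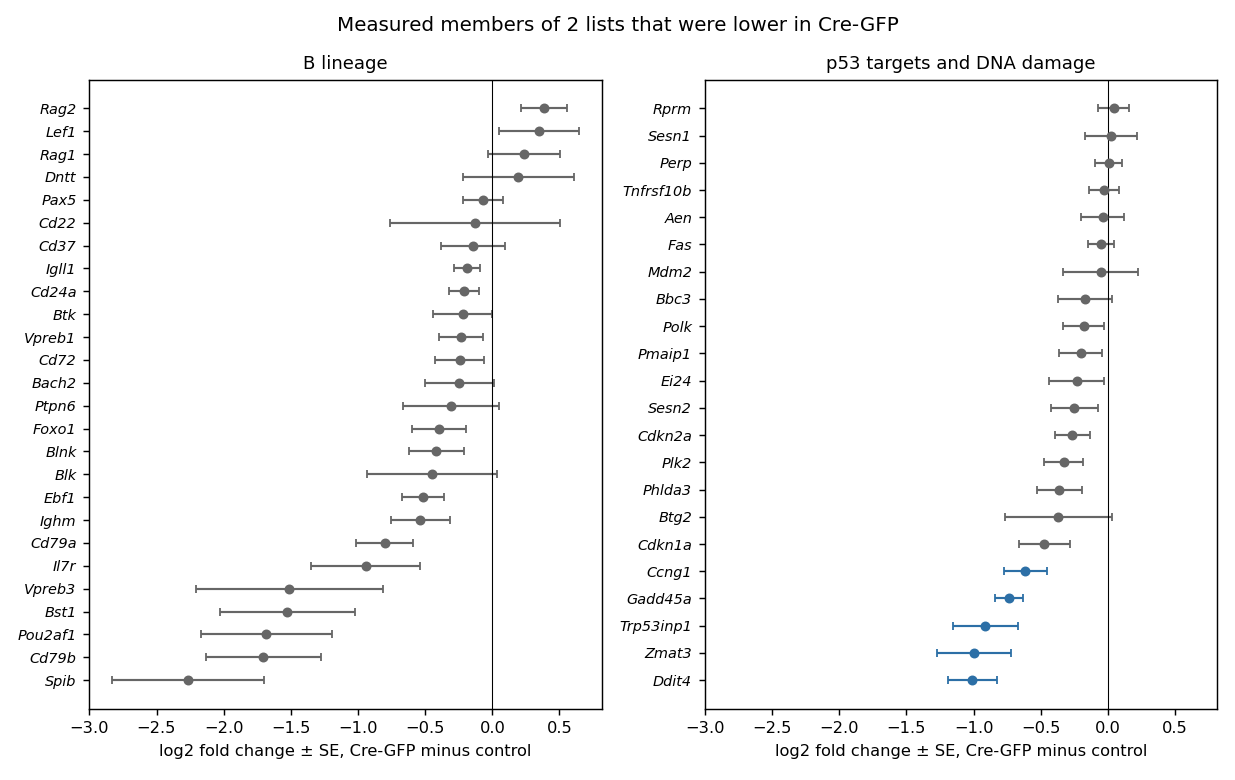
Points are limma's log2 fold changes, Cre-GFP minus control, and bars their SE, for the measured members of the B lineage list (left) and the p53 target list (right); blue marks an adjusted p under 0.05 over the list alone. The B lineage members run from −2.26 for Spib to 0.38 for Rag2, and 5 p53 targets are in blue.

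The interferon response list fell, with 14 of its 21 measured members lower and 7 higher, the highest at 0.67. When adjusted over the list alone 3 genes fell: Gbp2 (−2.52 ± 0.46, or 5.76-fold lower) and Gbp3 (−1.12 ± 0.18), which are interferon-gamma-inducible GTPases, and Ifi204 (−0.49 ± 0.10), a DNA sensor read at values under each array's 20th percentile (−0.0031 once they were raised to it). Without either Cre-GFP array, 0 of these 3 passed over the list. Gbp2 differed by −1.76 without control 2, −3.29 without control 1 and −1.67 on its other probe set, where it did not pass. Iigp1, another GTPase of this kind, differed by −0.69 ± 0.20 (−0.41 without control 2 and −0.35 on its other probe set) without passing. The list median was −0.14 (camera adjusted p = 0.0013, and adjusted p = 0.42 with an estimated correlation). It was −0.24 without Cre-GFP 1, −0.068 without Cre-GFP 2, −0.081 without control 2, −0.28 without the dimmest genes and −0.041 with dim values raised, passing camera each time.

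The immediate early and stress list also fell, with 16 of 24 members lower and none past over the list alone. Jun, Fos and the phosphatase Dusp1, all induced within minutes of a growth or stress signal, differed by −1.13 ± 0.28, −0.89 ± 0.26 and −0.72 ± 0.15. Chac1, a glutathione-degrading enzyme of the unfolded protein response, differed by −0.83 ± 0.30. Without control 2 the differences of Jun and Fos were −0.70 and −0.57, and without Cre-GFP 1 that of Chac1 was −0.42. The median was −0.11 (camera adjusted p = 0.0037, and adjusted p = 0.42 with an estimated correlation). It was −0.20 without Cre-GFP 1, −0.026 without Cre-GFP 2, −0.19 without control 1 and −0.24 without the dimmest genes, passing camera each time.

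Myc targets and ribosome biogenesis genes were higher in 16 of 19 cases, with small differences. Fbl, the methyltransferase of ribosomal RNA, differed by 0.24 ± 0.13, Srm, spermidine synthase, by 0.27 ± 0.17, Rrp9 by 0.26 ± 0.16 and Ldha, lactate dehydrogenase, by 0.50 ± 0.33. Srm differed by 0.09 without Cre-GFP 2 and 0.45 without Cre-GFP 1. Ldha differed by 0.21 and 0.80 in these settings, by 0.11 without control 1 and by 0.90 without control 2. None passed over the list alone. The list rose (median 0.24, camera adjusted p = 7.8e-04, and adjusted p = 0.46 with an estimated correlation). Without control 1 the median was 0.14, and without Cre-GFP 2 it was 0.12 and the list did not pass (adjusted p = 0.52). The list also passed camera when Cre-GFP 1 and control 2 were set against the other 2 arrays (median −0.13).

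Monocyte and macrophage markers were higher in 17 of 24 cases. Csf1r, the receptor for macrophage colony-stimulating factor, differed by 1.13 ± 0.34, with 0.17 to 0.36 on its other probe sets. Lyz1 and Lyz2, the lysozymes of myeloid cells, differed by 1.36 ± 0.54 and 0.98 ± 0.41, and Apoe by 0.37 ± 0.12. Lyz1 and Lyz2 differed by 0.53 and 0.37 without control 1 and by 2.20 and 1.59 without control 2, and the other Lyz1 probe sets by 1.33 and 0.19. None passed over the list alone. The list rose (median 0.11, camera adjusted p = 0.0054, and adjusted p = 0.64 with an estimated correlation), and it also passed when Cre-GFP 1 and control 2 were set against the other 2 arrays, with a median of 0.21. Single arrays decided this call: the median was −0.0042 without Cre-GFP 1 (adjusted p = 0.63) and 0.084 without control 1 (adjusted p = 0.19), against 0.24 without Cre-GFP 2 and 0.17 without control 2. It was 0.35 without the dimmest genes.

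**Figure D3:**
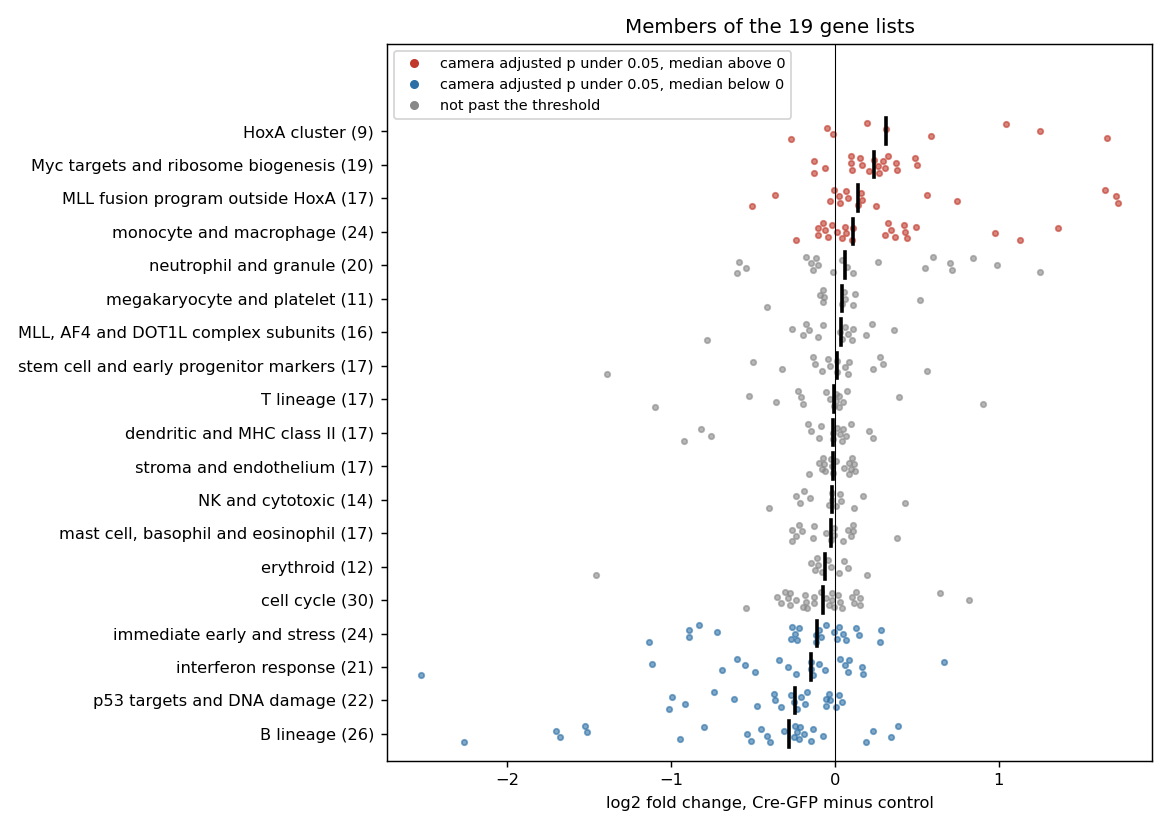
Each point is a measured member's log2 fold change, Cre-GFP minus control, for the 19 lists, with the number of members in parentheses and a black bar at the list median. Red and blue mark the 8 lists with a camera adjusted p under 0.05, with medians from −0.28 for B lineage to 0.32 for HoxA.

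The other 11 lists did not pass camera, and the median of 10 of them turned sign when some single array was left out. Neutrophil and granule genes had a median of 0.06 (adjusted p = 0.31), or −0.20 without control 1, and the list passed without control 2 (median 0.19) and without the dimmest genes (0.55). Within it 2 enzymes of the primary granules of early myeloid cells rose when adjusted over the list alone: Mpo (myeloperoxidase) was 2.38-fold higher (1.25 ± 0.15) and Ctsg (cathepsin G) differed by 0.99 ± 0.15, and both passed without any single array. S100a8, a calcium-binding protein of mature neutrophils named after its values were seen, read 10.47 and 11.07 in Cre-GFP and 8.98 and 11.47 in control. Cell cycle genes had a median of −0.07 (adjusted p = 0.056), past the threshold without Cre-GFP 2 (median −0.12, adjusted p = 0.022) and with dim values raised (adjusted p = 0.030), with Ccnd2 at 0.82 ± 0.39 (0.20 to 0.93 on its other probe sets) and Ccnd3 at −0.54 ± 0.26, the D-type cyclins of lymphoid cells. Without control 2 these 2 differed by 0.34 and −0.20, without control 1 by 1.30 and −0.88, and Ccnd2 by 0.43 without Cre-GFP 1. Dendritic and MHC class II genes had a median of −0.01 (adjusted p = 0.31), or −0.052 without control 2, where they passed (adjusted p = 0.024). Of these, H2-Ab1, an MHC class II chain, fell by 0.92 and Ccr7, a lymph node homing receptor, by 0.75 when adjusted over the list alone. Other H2-Ab1 probe sets differed by −0.09 and −0.41. H2-Ab1 and Ccr7 missed with the replicate number as a block. These did not pass over the list without either Cre-GFP array, nor Ccr7 without control 1.

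Erythroid genes had a median of −0.06 (adjusted p = 0.31), and carbonic anhydrase Car2 was the 1 member that fell over the list alone (−1.46 ± 0.18, 2.75-fold lower), also without any single array. T lineage genes had a median of −0.00 (adjusted p = 0.52). The costimulatory receptor Cd28 (0.90 ± 0.19) and the T cell transcription factor Bcl11b (0.39 ± 0.09) rose over that list alone, with 0.26 on a second Cd28 probe set. Bcl11b lay at values under the 20th percentile, and raising them turned its difference to −0.0031. Neither gene passed with the replicate number as a block. Cd28 did not pass over the list without Cre-GFP 2 or control 2, nor Bcl11b without either Cre-GFP array or control 2. Stem cell and early progenitor markers had a median of 0.01 while their camera direction was down (adjusted p = 0.85), and Egr1, an immediate early factor also active in quiescent stem cells, fell over the list alone (−1.39 ± 0.21), a call lost without Cre-GFP 2. MLL, AF4 and DOT1L complex subunits had a median of 0.04 and a camera direction of down (adjusted p = 0.90), with Psip1, which tethers MLL to chromatin, at −0.78 ± 0.20 (−0.21 on its other probe set). Medians were −0.02 for NK and cytotoxic (adjusted p = 0.44), −0.02 for mast cell, basophil and eosinophil (adjusted p = 0.52), 0.04 for megakaryocyte and platelet (adjusted p = 0.91) and −0.01 for stroma and endothelium genes, whose camera direction was up (adjusted p = 0.90). No member of the MLL complex, NK, mast cell, megakaryocyte or stroma lists passed over its list alone.

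Outside the lists, the highest-ranked differences included genes of several functions, none past the threshold over all genes (adjusted p from 0.15 to 0.27 in limma). Higher in Cre-GFP were Grtp1 (6.19-fold, 2.63 ± 0.28), a GTPase-activating protein, and Egln3 (4.02-fold, 2.01 ± 0.22), an oxygen-sensing prolyl hydroxylase with 0.70 on its other probe set. Zcchc7, an RNA-binding subunit of a nuclear RNA surveillance complex, was 3.03-fold higher. Tmem40, Hexa (a lysosomal hexosaminidase chain), Tjp1 (a tight junction scaffold) and Mylk (myosin light chain kinase) were 2.44- to 2.75-fold higher, with 0.56 on a second Tmem40 probe set and 0.00 and 1.14 on the other Mylk probe sets. Lower in Cre-GFP were Alpl (3.83-fold, −1.94 ± 0.23), alkaline phosphatase, Fcrla (3.65-fold, −1.87 ± 0.22), an Fc receptor-like protein of B cells, and Ifi209 (3.59-fold). Fcrla's other probe sets differed by only −0.11 and −0.14. Pfn2, an actin-binding profilin, was 3.31-fold and Capn2, a calpain protease, 3.12-fold lower. Csf1 (macrophage colony-stimulating factor, with its 4 probe sets from 0.00 to −1.32), Gbp2b, Ccn3 and Pik3cg, the leukocyte kinase PI3K gamma, were 2.25- to 2.50-fold lower.

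In limma, 0 of 12394 genes had an adjusted p under 0.05, with the smallest at 0.15, and 600 had an unadjusted p under 0.05 (286 higher, 314 lower) where 620 would by chance. At an unadjusted p under 0.001 there were 41 genes against 12.4 by chance. The limma fit behind these counts leaves differences between arrays 1 and 2 in its error. With the replicate number as a block, 952 genes had an unadjusted p under 0.05 in limma and 0 passed after adjustment. The ordinary two-sample test with pooled variance called 2 genes (557 at an unadjusted p under 0.05), Klf1 and Nsun5, which differed by 0.03 and 0.33 with nearly identical replicates. Group means lay at least 2-fold apart for 91 genes (41 higher, 50 lower). The groups of 88 of these did not overlap, which the choice of genes with so large a gap makes likely by itself. Over all genes, 30.0% had groups that did not overlap, where chance gives 33.3% for 2 against 2. Replicates differed about as much as the groups did: the SD of the log2 difference over genes was 0.28 within Cre-GFP and 0.32 within control, and 0.27 to 0.37 between a Cre-GFP and a control array. Without control 1 the adjusted count was 135 (927 at an unadjusted p under 0.05), without control 2 it was 34 (635), without either Cre-GFP array it was 0 (496 and 519), and with values raised to the 20th percentile it was 29 (634).

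In 4 of 4 measures of 3' bias the group means differed by less than the larger of the 2 differences within a group. For Gapdh 3' against 5' the group means differed by 0.13, which was more than the control arrays differed. The log2 excess of the 3' over the 5' probe set of Gapdh was 3.99 and 4.32 in Cre-GFP 1 and 2 and 4.32 and 4.24 in control 1 and 2, and for beta-actin 3.36 and 3.04 against 3.60 and 2.81. Hybridization spike-ins (18 probe sets) lay 0.41 above the mean of the 4 arrays in control 1 and between −0.22 and −0.05 in the other arrays.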

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

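The same 8 lists passed camera after quantile normalization again, after centring, with eBayes without trend or with robust estimation, with the mean of a gene's probe sets and without shared probe sets. Named genes had no call over all genes to lose. Of the 24 members past over their list alone, 24 passed after centring and with robust estimation, 21 after quantile normalization again, 16 without trend, 19 with the mean of probe sets and 20 with dim values raised. Without the dimmest genes 16 of 19 measured members passed, and 14 of 18 without shared probe sets, where Hoxa10, Meis1, Lmo2, Bcl11b, H2-Ab1 and Gbp3 were not measured and Igf2bp3 (0.35), Cd28, Ccr7 and Gbp2 (−1.67) missed; Fcrla (−0.11) and Lyz1 (0.19) were also small there. Among values that had not passed, the mean of probe sets turned Hoxa3 (0.07), Hoxa4 (0.01) and the medians of the MLL complex (−0.0032), stroma (0.0028) and T lineage lists (0.0051). Leaving out shared probe sets turned Prf1 (0.08), Lepr (0.12) and the NK (0.0046) and dendritic (0.030) medians. Leaving out the dimmest genes turned the stem cell (−0.032), NK (0.14) and stroma (0.0081) medians. Genes at an unadjusted p under 0.05 numbered 383 without the dimmest 40% of genes and 1092 over all probe sets (fewer genes and more probe sets tested). With values raised to each array's 20th percentile 29 genes passed, 26 of them at least 2-fold. That floor turned 8 named genes: Hoxa2, Tal1, Bcl11b, Cd83, Vwf, Col1a1 and Cxcl12 to −0.0031 each, the difference of the group floors, and Pdgfra to −0.0075. It turned the stem cell, neutrophil and megakaryocyte medians to −0.0031 and let the cell cycle list pass (median −0.0696; the cause was not tested). The ordinary two-sample test called 2 genes. The neutrophil list passed without the dimmest genes (median 0.55, fewer members tested). With an estimated correlation, and with fry, camera's 8 lists missed the threshold. Their medians were unchanged at 0.32 (HoxA), 0.14 (MLL program), −0.28 (B lineage), −0.24 (p53), −0.14 (interferon), −0.11 (immediate early), 0.24 (Myc) and 0.11 (monocyte). Camera with an estimated correlation also rests on 2 residual degrees of freedom, so its misses need not come from correlation among members. The cell cycle list had an estimated correlation of −0.023, and its unadjusted camera p still went from 0.027 to 0.13. How far correlation among members accounted for the misses was not tested.

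Leaving out each array, which assumes that the lone array varies like the other group, gave 0 to 135 genes, 0 to 118 of them at least 2-fold, and 496 to 927 at an unadjusted p under 0.05, the highest without control 1. Of the 24 members, 13 passed without Cre-GFP 1, 8 without Cre-GFP 2, 21 without control 1 and 16 without control 2, and 8 passed each time: Hoxa5, Hoxa9, Meis1, Igf2bp3, Lmo2, Mpo, Ctsg and Car2. List medians ranged from −0.0042 to 0.24 for monocyte, 0.12 to 0.28 for Myc, −0.20 to 0.19 for neutrophil, −0.13 to 0.063 for dendritic and −0.12 to −0.054 for cell cycle genes. The neutrophil and dendritic lists passed without control 2 and the cell cycle list without Cre-GFP 2; the cause was not tested. No detection calls were used, so how far signals lay above background limits what can be said of dim genes.

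With the replicate number as a block (replicate block), 952 genes had an unadjusted p under 0.05 and 0 passed, and the same 8 lists passed camera. Of the 24 members 16 passed, without Hoxa10, Cd28, Bcl11b, H2-Ab1, Ccr7, Ccng1, Trp53inp1 and Zmat3; it changed no other call. The differences between arrays 1 and 2 of the groups correlated across genes (r = 0.35), which the labels do not explain; genes are not independent replicates. The correlation was 0.34 after an intensity trend was removed and 0.35 after a gene span trend was removed, against either trend as the whole cause. In a test chosen after the result was seen, 5 of 11 cell marker lists differed between arrays 1 and 2 with opposite signs in the groups and 6 with the same sign, so a shared difference in cell mixture remains open. A processing day or batch also remains open and was not tested.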

Other observations

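Several genes outside the named set, chosen after their values were seen, lay at least 2-fold apart without passing the threshold over all genes. Mycn, a Myc-family factor of early B cell progenitors, had the largest of these negative differences (−2.78 ± 0.45), from 13.63 and 13.49 in control to 11.53 and 10.02 in Cre-GFP on the log2 scale. Fcgr2b, the inhibitory Fc receptor of B cells, differed by −1.86 ± 0.31, Trib2, a pseudokinase, by −1.92 ± 0.33 and Klf2, a lymphocyte quiescence factor, by −1.24 ± 0.13. Higher in Cre-GFP were the interferon-induced transmembrane proteins Ifitm3 (1.57 ± 0.25) and Ifitm1 (1.21 ± 0.27). Ifitm3 and Ifitm1 are not on the interferon response list and went against its fall. Ifi209 (−1.84 ± 0.29) and Gbp2b (−1.29 ± 0.18), relatives of the listed Ifi204 and Gbp2 and also outside the list, were lower. Also higher were the tetraspanin Cd9 (1.07 ± 0.17), the chromatin organizer Satb1 (1.26 ± 0.26) and the insulin receptor substrate Irs1 (2.03 ± 0.56, and 1.19 without Cre-GFP 1).

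Further members of the B lineage list, also named after their values were seen, differed in size and sign. The surrogate light chain genes Igll1 and Vpreb1, among the brightest on the arrays with mean intensities of 14520 and 12305 in control, differed by −0.19 ± 0.10 and −0.23 ± 0.16, and Vpreb1 by −0.02 without control 2 and −0.44 without control 1. Vpreb3, a related gene of B cell precursors, differed by −1.51 ± 0.69, or −0.40 without control 2 and −2.62 without control 1. Ebf1, the factor that commits cells to the lineage, differed by −0.51 ± 0.16 and the recombinase gene Rag2 by 0.38 ± 0.17. Dntt (0.19 ± 0.41), Rag1 (0.23 ± 0.27) and Pax5 (−0.07 ± 0.15) turned sign with a single array left out, to −0.49 without control 1, −0.07 without Cre-GFP 2 and 0.10 without control 1. None of these passed over the list alone.

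The tests of monocyte share, 3' bias and splits of the arrays were chosen after the results they bear on were seen; those of the HoxA neighbourhood and of B lineage share were written before.

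The 8 HoxA and MLL program genes that passed over their lists alone had a median log2 fold change of 1.45. A difference in 3' bias would separate the groups by more than their own arrays. In 4 of 4 control measures, all from Gapdh and beta-actin, the group means differed by less than the larger difference within a group. With 2 arrays per group a moderate bias could also give this, so 3' bias is not excluded. A change spread over the chromosome region would raise the neighbours of the cluster. The 13 measured genes among the 10 on either side had a median of −0.08775 (95% bootstrap interval −0.12 to 0.039). This argues against a rise shared by most of them, while single genes ran from −0.36 to 0.46 (Chn2, ± 0.15). The interval treats the genes as replicates and leaves out the error between arrays, and it was not repeated with single arrays left out. A larger share of monocytes remains open: the 9 monocyte list members above the array median had a median lower than that of the 8 genes by 1.03 (95% bootstrap interval 0.064 to 1.55), but the interval reached −0.38 without Cre-GFP 2 and −0.73 without control 2, and the 8 genes had been picked because they passed. Of these members Lyz1, Csf1r and Lyz2 differed by 1.36, 1.13 and 0.98, and within groups the 8 genes went with the monocyte list in 1 of 2 pairs. Shares of cells other than monocytes, early myeloid cells and progenitors among them, were not tested for these genes and also stay open. The activated fusion named by the design may raise these genes, a hypothesis that these arrays do not separate from the presence of Cre.

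The B lineage list was lower in Cre-GFP, and a lower share of B lineage cells would lower genes made by them alike. The 25 members above the array median differed among themselves by more than their errors (heterogeneity 80.95, against a simulated 95th percentile of 64.45, and a share of 0.0157 of 10000 simulations as large). The simulation drew each gene's error independently and was not repeated with single arrays left out. It therefore does not decide whether a lower share of B lineage cells is the whole cause. That test also takes the members to come from B lineage cells, while Ptpn6, Btk and Foxo1 are also made by other blood cells. A smaller share, as part or whole of the change, stays open. The activated fusion named by the design also stays open and was not tested apart from Cre.

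The 4 arrays can be split into pairs in 3 ways, too few for a share under 0.05. In the real split 600 genes had an unadjusted p under 0.05, and the highest other split, number 1 against number 2, had 1397, so 2 of 3 splits gave as many; this points to a structure of the arrays by number. At an unadjusted p under 0.001 the counts were 41 in the real split, 23 by number and 2 in the crossed split. Camera passed 8 lists in the real split, 0 by number and 3 in the crossed split, which were B lineage (median 0.28), monocyte (0.21) and Myc targets (−0.13). The HoxA median was 0.32, 0.12 and 0.0030 in these splits.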
